A study of Mus musculus with 4 samples.

How the data were processed

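The data are single-cell RNA sequencing of immune cells of the mouse retina, made with the 10x Genomics Chromium Single Cell 3′ kit from viable CD45+ cells sorted by flow cytometry. There are 4 libraries, with 1 library in each of 4 groups: an NaIO3 model, a P23H model, an aging model and a young control. The labels do not say how many animals or retinas were pooled in a library, and they give neither a dose nor a time for NaIO3.

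The deposited values are UMI counts, whole numbers per gene and cell, with no normalization by the authors. Per the submitters' processing notes, reads were handled with Cell Ranger and STAR on the mouse build mm10, whose versions are not given in the sources used here. Per the file headers, the matrix was written by software version 3.0.1 and holds all 4 libraries, with 31053 genes and 6529 barcodes. The number after the dash of each barcode gives the library, as described in the labels. Gene positions came from GENCODE release M21. Of the 31053 gene identifiers, 30934 were found in that annotation (99.6%).

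Cells were kept if they had at least 500 UMIs and 250 genes and at most 10% mitochondrial UMIs, which 6225 cells met. Doublets were predicted in each library with Scrublet, as implemented in scanpy, with an expected doublet rate of 5%. It called 44 of the 6225 cells (0.707%), and 6181 cells were left. Counts were scaled to 10000 per cell and logged, 2000 variable genes and 30 principal components were taken, and a graph of 20 neighbours was clustered with the Leiden algorithm at resolution 1 and seed 1, giving 20 clusters. The libraries were not aligned to each other before clustering, since library and group are the same thing in this design.

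Clusters were named with 20 marker lists. A cluster took the name of a class other than microglia when its 10 genes of highest fold over the other clusters held at least 2 markers of that class. Any other cluster took the class whose markers had the highest mean share of cells with a UMI. A cluster was left unnamed if fewer than 3 markers were detected, or if its median UMI count was under 1/3 of that of its library with no marker of its own class among those 10 genes. That left 1 shallow cluster unnamed. As a check, each cluster was compared with the cells of other classes, and the 10 genes so found held at least as many markers of its own class as of any other. The cycling cluster held 0 of either. The Gpnmb-led and Cst7-led microglia-like clusters listed Cox6a2, which is on the plasmacytoid dendritic cell list, so the results were also computed without these clusters. Class names end in "-like" because no protein or spatial measurement stands behind them.

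For each class and library the UMIs of all cells were summed and scaled to the class total, as CPM. Log2 ratios of CPM were taken between libraries for genes with at least 10 UMIs in the pair. Sums carry exact Poisson intervals, ratios carry the interval of the binomial split of the counts between the libraries, and shares carry exact Clopper-Pearson intervals, all at 95%. All of these cover counting error only, not the variation between animals. A ratio against a library with 0 UMIs is a bound against a floor of 3 UMIs, and a share of 0 is given the upper limit of 3 counts of its total in place of the Clopper-Pearson limit. With 1 library per group there is no replicate, so no test was made, no p-value is given and no genes are counted as changed. Cells were not used as replicates.

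Each of 15 gene lists was described by its median log2 ratio, with an interval from 1000 Poisson draws of the counts, and by the percentile of that median among 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these libraries only. Clec7a, a member of the degeneration-associated list, is absent from the features, which leaves 29 of its 30 genes. For scores per cell, each cell was thinned to 2000 UMIs and shallower cells were left out, and the share of UMIs from the degeneration-associated list was compared with the 95th percentile of the young control. Shares of cells with a UMI of a single gene were compared after thinning to 1000 UMIs.

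The groups, comparisons, gene lists, marker lists and named-gene rule were fixed before the data were examined, as were all alternatives except those named as chosen later. For each model against the young control, the rule takes the 10 genes with the highest and the 10 with the lowest ratio in microglia-like cells, among genes with at least 50 CPM in either library and 30 UMIs in the pair. It leaves out mitochondrial, ribosomal protein, Gm-numbered and Rik genes and markers of non-immune cells. P23H against NaIO3 takes 5 each way. Any other class with at least 100 cells in both libraries takes 5 each way at 100 CPM. Up to 4 members of each list are named by the size of their ratio, and Lgals3, Trem2, Apoe, P2ry12, Tmem119, Cx3cr1 and Ccr2 are always given. Members of a list given in addition, to show its most abundant genes, were chosen after their values were seen.

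The handling was tested on simulated data, in which 200 genes were moved by known amounts in counts drawn from the young control. The sign was recovered for 100% of them. The interval held the true value for 93.0% to 98.0% of genes. Of 200 unmoved lists, 6, 9 and 11 fell outside the central 95% of random lists in the NaIO3, P23H and aging simulations. Because the 3 model libraries share 1 control, similarity between their ratios was compared with 100 simulations in which only the control was shared, and with a control split in 2. All simulated counts were drawn from 1 pooled profile, so they hold counting error only.

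The alternatives were no filter on cells, a stricter filter (1000 UMIs and 5% mitochondrial UMIs), doublets kept, cluster resolutions of 0.5 and 2, edgeR TMM scaling, totals without mitochondrial and ribosomal protein genes, equal weight for each cell, thinned cells, a minimum of 50 UMIs or none, the 90th percentile, thinning to 1000 UMIs or none, and the degeneration-associated list without Apoe, Fth1, Cd52 and Tyrobp. Alternatives chosen after seeing the data removed the 5% of cells with the highest doublet score, took immune cells as the denominator, counted the unnamed cluster or the Mmp12-led macrophage-like cluster as microglia-like, or left out the Gpnmb-led cluster, alone or with the Cst7-led one. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.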

Results

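Gene expression was measured cell by cell in CD45+ immune cells sorted from mouse retinas, in 4 libraries. The NaIO3 library came from wild-type mice of 60 days given sodium iodate, which is toxic to the retinal pigment epithelium. The P23H library came from mice of 60 days that carry the P23H allele of rhodopsin, the light-sensing protein of rods, in which rods degenerate. The aging library came from mice of 2 years, and the young control from wild-type mice of 60 days. Each group was 1 library, so the values have no replicates and every interval covers counting error only. The libraries held 13308579 (NaIO3), 9124295 (P23H), 3983257 (aging) and 2985796 (young control) UMIs in 2903, 2032, 907 and 687 barcodes. After filtering, 2818, 1839, 863 and 661 cells were kept, with median UMI counts per cell of 4474, 4388, 4148 and 4322. By its title and labels, the series set out to profile retinal immune cells across models of outer retinal degeneration.

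Microglia-like cells, marked by P2ry12 and Tmem119, were the largest class in each library, and lymphocytes and macrophages took a larger share in some models. Microglia-like cells made up 67.8% of young control cells (95% interval 64.1 to 71.3), 78.5% of NaIO3 cells (77.0 to 80.0), 55.0% of P23H cells (52.7 to 57.3) and 47.5% of aging cells (44.1 to 50.9). T-cell-like cells made up 13.4% of the aging library (11.2 to 15.9, 116 cells) and 6.04% of the P23H library (4.99 to 7.22, 111 cells). In the NaIO3 library they were 1.28% (0.896 to 1.76, 36 cells) and in the young control 0.756% (0.246 to 1.76, 5 cells). Macrophage-like cells, marked by Mrc1 and Ms4a7, made up 19.6% of aging cells (17.0 to 22.4), 10.3% of P23H cells, 6.99% of NaIO3 cells and 8.77% of young control cells (6.73 to 11.2). With the 5% of cells of highest doublet score removed, the macrophage-like shares were 11.4%, 5.44%, 3.43% and 2.98% in the same order. Much of that fall came from cells newly classed as microglia-like, not from cells removed. These were 62 of 156 remaining macrophage-like cells in aging and 73 of 168 in P23H. In NaIO3 they were 93 of 185 and in the young control 37 of 56.

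Monocyte-like, neutrophil-like and natural-killer-like cells were few in each library. Their shares were highest in the P23H library, but in each class its interval overlapped that of another library. Monocyte-like cells, marked by Plac8 and Ace, made up 2.28% of P23H cells (1.65 to 3.07), 2.09% of aging cells (1.24 to 3.28), 0.426% of NaIO3 cells and 0.454% of young control cells. Neutrophil-like cells, marked by S100a8 and S100a9, were 4.02% of P23H cells (3.17 to 5.03), 2.09% of aging cells (1.24 to 3.28), 1.03% of NaIO3 cells and 1.21% of young control cells. Natural-killer-like cells were 2.45% of P23H cells (1.79 to 3.26, 45 cells) and 2, 5 and 8 cells in the aging, NaIO3 and young control libraries. The young control share was 1.21% (0.524 to 2.37). The aging share of 0.232% was 1.33% with no filter on cells, 1.55% with the stricter cell filter and 1.38% with doublets kept. B-cell-like cells were 3.92% of P23H cells and 1.62% to 1.82% of the others. The CD45 gate should remove photoreceptors, yet photoreceptor-like cells were 11.95% of young control, 10.2% of P23H, 6.72% of aging and 4.72% of NaIO3 cells (5.25%, 4.19%, 3.74% and 1.76% with the stricter cell filter), and an unnamed shallow cluster was 3.48% to 4.99% of each library. Of immune cells alone, microglia-like cells were 82.7% in the young control, 87.1% in NaIO3, 65.4% in P23H and 54.9% in aging, in the same order as among all kept cells.

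**Figure D1:**
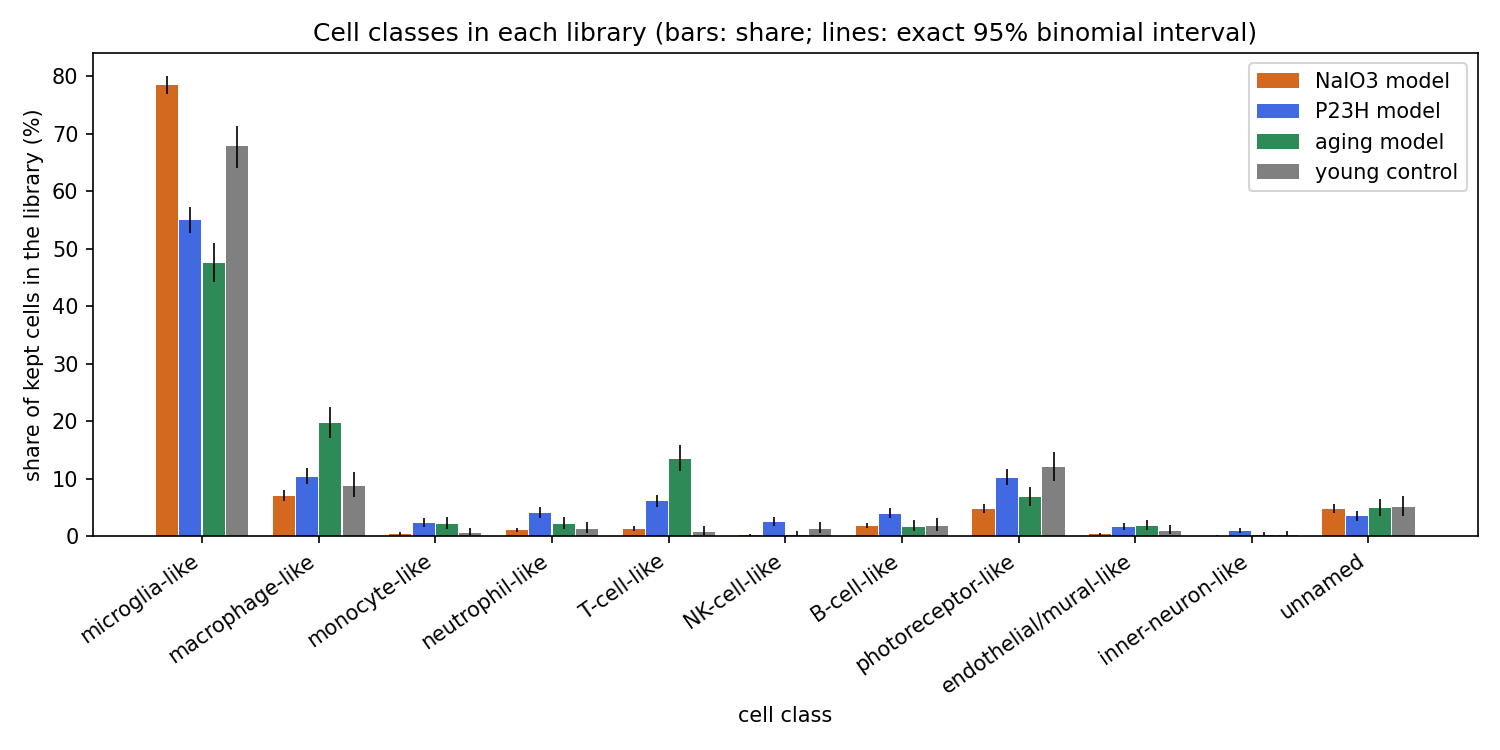
Share of kept cells (%, y axis) in each cell class (x axis) for each of the 4 libraries, with exact 95% binomial intervals as lines. Microglia-like cells run from 47.5% in the aging library to 78.5% in the NaIO3 library, and T-cell-like cells reach 13.4% in the aging library.

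The microglia-like class held 7 clusters, whose mix differed between libraries. A cluster led by Plk3, Hbegf and Klf2 held 64.7% of microglia-like cells of the young control against 24.0% in NaIO3, 11.0% in P23H and 36.1% in aging. A cluster led by Gpnmb, Spp1 and Gdf15 held 15.2% in P23H against 2.03% in NaIO3, 0.976% in aging and 1.12% in the young control. An interferon-led cluster (Ifit3, Mx1) held 11.9% in NaIO3, 13.6% in P23H, 10.0% in aging and 4.91% in the young control. A cycling cluster (Top2a, Birc5) held 1.85%, 3.56%, 2.93% and 1.12% in the same order, and its cells are part of the cell cycle values below. The values below sum all 7 clusters, over 10963174 UMIs of 2213 cells in NaIO3, 5838360 of 1011 in P23H, 1958684 of 410 in aging and 2174718 of 448 in the young control, and are CPM of those totals. Markers of other cells in this class, in the order NaIO3, P23H, aging and young control, were 84.2, 139, 236 and 34.0 CPM for macrophages, 533, 818, 522 and 466 for monocytes, 12.8, 14.2, 33.2 and 9.20 for T cells, 0.639, 7.71, 1.53 and 1.84 for natural killer cells, 13.7, 56.2, 39.8 and 9.20 for plasmacytoid dendritic cells, and 284, 335, 271 and 242 for rods. Müller glia markers stood at 2405, 1930, 1748 and 2715 CPM and pigment epithelium markers at 7.84, 13.2, 9.70 and 7.36 CPM. The median mitochondrial share of UMIs per microglia-like cell was 1.13%, 1.37%, 1.23% and 0.843%, higher in each model than in the young control.

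What set microglia-like cells of the NaIO3 library apart from the young control was a higher level of interferon-response genes and a lower level of genes such as Plk3 and Klf2, with a smaller rise in the median of degeneration-associated genes, beside homeostatic genes whose median lay near that of the control. Gpnmb, a lysosomal membrane glycoprotein (ENSMUSG00000029816, mm10 chromosome 6, 49036546 to 49070929), was 78.5-fold higher (95% interval 21.6 to 649), with 791 UMIs against 2. Lgals3, which encodes the sugar-binding protein galectin-3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160), was 6.82-fold higher (4.55 to 10.7). Spp1, which encodes osteopontin (ENSMUSG00000029304, chromosome 5, 104435118 to 104441050), was 5.99-fold higher (4.86 to 7.45). These transcripts sat in few cells: Gpnmb UMIs came from 34 of 2213 NaIO3 cells, and 1 NaIO3 cell held 1722 of its 2777 Spp1 UMIs. Without that cell Spp1 stood at 96.2 CPM against 42.3 in the young control, where 64 of 92 UMIs also came from 1 cell. Without the Gpnmb-led cluster Gpnmb was 2.02-fold and Lgals3 1.71-fold higher, and Spp1 turned to a log2 ratio of -0.18. With equal weight for each cell Gpnmb, Lgals3 and Spp1 were 33.4-fold, 3.94-fold and 3.75-fold higher.

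Of the degeneration-associated list, 24 of 29 members were higher and 5 lower in NaIO3, with a median log2 ratio of 0.37 (0.25 to 0.42, percentile 100), and of 0.13 with the stricter cell filter. The list's median share of UMIs per cell was 3.00% against 3.05% in the young control. Ch25h, which makes 25-hydroxycholesterol, had 120 UMIs against 1 (23.8-fold, 4.19 to 948). Apoe, the main lipid carrier of glia (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), was 1.20-fold higher (1.15 to 1.25). The microglial lipid receptor Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) was at 1.01-fold (0.977 to 1.05). All 20 interferon-response genes were higher, with a median of 1.06 (0.99 to 1.23). Rtp4 was 4.08-fold (3.06 to 5.58), the antiviral GTPase gene Mx1 3.85-fold, Ifi27l2a 3.76-fold (3.25 to 4.37) and the 2′-5′-oligoadenylate synthetase-like gene Oasl2 3.44-fold higher. Ifit2, Ifit3 and the transcription factor gene Stat1 were 2.31-fold, 2.28-fold and 2.26-fold higher. The cystine transporter gene Slc7a11 was 2.28-fold and Rmi2, of the DNA repair machinery, 2.54-fold higher.

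The homeostatic list, genes that mark resting microglia, had a median of 0.03 in NaIO3 (-0.03 to 0.06, percentile 34.6), with 11 members higher and 9 lower. P2ry12, a purine receptor, had a log2 ratio of -0.18, Tmem119 of -0.05 and the fractalkine receptor gene Cx3cr1 of 0.11. Mafb, a macrophage transcription factor gene, was at -0.81 and Fcrls at 0.37. Ccr2, the receptor that marks inflammatory monocytes, gave 4 UMIs against 1, a ratio of 0.793 with an interval of 0.0785 to 39.1. Of the NaIO3 genes with the lowest ratios, the kinase gene Plk3 (ENSMUSG00000028680, chromosome 4, 117128655 to 117133963) was 11.3-fold lower (9.94 to 12.9) and the transcription factor gene Klf2 (ENSMUSG00000055148, chromosome 8, 72319033 to 72321656) 6.73-fold lower (6.43 to 7.04). Yrdc, Rnf187 and Snta1 were 9.72-fold, 8.28-fold and 8.14-fold lower. Pnrc1, Cebpa, Dusp5, Zfand5 and Jund were 7.46-fold, 7.17-fold, 6.70-fold, 6.05-fold and 6.00-fold lower. The lowest 50 NaIO3 genes were lower in macrophage-like cells too, all 50 of them, with a median log2 ratio of -1.53. Their transcripts had a median GC content of 52.8%, against 49.3% over all genes compared.

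Among the other lists in NaIO3, 5 of 8 measured MHC class II genes were higher, with a median of 0.44 (0.20 to 0.68) and 4 of the 8 intervals including no change. H2-Aa was 3.81-fold, H2-Eb1 3.00-fold, H2-Ab1 1.64-fold and the invariant chain gene Cd74 1.43-fold higher. With equal weight for each cell, H2-Aa was 1.57-fold and H2-Eb1 1.35-fold higher. The direction of this list rests on where macrophage-like cells end: with the Mmp12-led macrophage-like cluster counted as microglia-like the median was -0.85. Markers of macrophages stood at 84.2 CPM in these cells against 34.0 in the young control. Cytokine and chemokine genes had a median of 0.28, with 13 of 21 higher, among them the chemokine genes Ccl7 (6.09-fold) and Ccl12 (1.83-fold) and the cytokine gene Il6 (2.62-fold). That median turned to -0.06 with the stricter cell filter. Ccl7 also led a macrophage-like cluster, and 1 NaIO3 microglia-like cell held 156 of its 491 UMIs. MHC class I had 10 of 13 genes higher (median 0.15, percentile 86.8), led by its activator Nlrc5 with 44 UMIs against 2, and by H2-Q7, Tap1 and Psmb8 at 1.46-fold, 1.44-fold and 1.22-fold. The immediate early list had 15 of 20 genes lower (median -0.21), among them Ier5 (3.99-fold lower) and Fosb (log2 ratio -0.66) beside Jund and Klf2.

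Metabolic, complement and cell cycle lists had smaller medians in NaIO3 than the interferon list. Oxidative phosphorylation had 25 of 27 genes higher (median 0.25), with Cox8a and Cox4i1 1.37-fold and 1.34-fold higher, and ribosomal protein genes were all higher, 21 of 21 (median 0.31), with Rpl32 1.41-fold higher. Lipid handling had 15 of 24 higher (median 0.17), with the cholesterol exporter genes Abcg1 and Abca1 3.08-fold and 2.12-fold higher. Complement had 8 of 12 higher (median 0.17), with C4b at 1.90-fold (0.873 to 4.90). Glycolysis had 12 of 17 higher (median 0.12) and the lysosome and phagocytosis list 21 of 29 (median 0.08), with the receptor gene Axl 1.51-fold higher and Lamp1, a lysosomal membrane protein gene, 5.87-fold lower. The cell cycle list had 14 of 20 higher (median 0.18), with Birc5 2.86-fold higher. The iron and antioxidant list had 13 of 21 higher (median 0.03), with Gclc 1.67-fold lower. The glycolysis and cell cycle medians turned to -0.03 and -0.06 with thinned cells, and the lipid median to -0.03 with the Mmp12-led cluster added.

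Microglia-like cells of the P23H library carried degeneration-associated genes at a higher median ratio than those of the other models, beside lower levels of most homeostatic genes. Gpnmb was 193-fold higher than in the young control (53.2 to 1594, 1035 UMIs against 2) and Lgals3 16.6-fold (11.1 to 26.0). H2-M2, a nonclassical MHC class I gene (ENSMUSG00000016283, chromosome 17, 37480851 to 37483552), was at least 56.6-fold higher, with 456 UMIs against 0. Apoe was 4.85-fold higher (4.67 to 5.03), at 6698 CPM in microglia-like cells of P23H, where it stood at 5019 CPM in photoreceptor-like and 380 CPM in T-cell-like cells. Cst7, a cysteine protease inhibitor gene (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), was 7.40-fold (5.63 to 9.92) and the fatty acid binding protein gene Fabp5 7.71-fold higher (5.44 to 11.3). Gpnmb came from 43 of 1011 P23H cells and H2-M2 from 19. Without the Gpnmb-led cluster the ratios were 6.58-fold for Gpnmb, at least 2.04-fold for H2-M2, 2.96-fold for Lgals3, 3.38-fold for Fabp5 and 7.54-fold for the stress cytokine gene Gdf15, which was 13.3-fold higher with it. With equal weight for each cell Gpnmb was 115-fold and H2-M2 at least 27.8-fold higher.

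Of the degeneration-associated list, 27 of 29 members were higher in P23H and 2 lower, with a median log2 ratio of 1.08 (0.95 to 1.18, percentile 100). Without the Gpnmb-led and Cst7-led clusters the median was 0.74. Ch25h had 74 UMIs against 1, and Trem2 was at 1.04-fold (1.01 to 1.08). The homeostatic list had 17 of 20 members lower, with a median of -0.28 (-0.29 to -0.21, percentile 1.10). The fructose transporter gene Slc2a5 had a log2 ratio of -0.67, P2ry12 of -0.51, Gpr34 of -0.50, P2ry13 of -0.48 and Tmem119 of -0.30. Cx3cr1 was at -0.08, and at 0.00 with TMM scaling and 0.04 without the Gpnmb-led cluster. Of the interferon list, 19 of 20 members were higher, with a median of 1.02 (0.82 to 1.13), led by Ifi27l2a (6.19-fold, 5.34 to 7.20), Rtp4 (3.72-fold), Oasl2 (3.43-fold) and Slfn2 (2.46-fold).

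Of antigen presentation genes in P23H, 11 of 13 of MHC class I (median 0.56) and 7 of 8 of MHC class II (median 0.77, 0.64 to 1.16) were higher, but 4 of the 8 class II intervals included no change. H2-Aa was 8.96-fold (5.80 to 14.6), H2-Eb1 6.50-fold, Cd74 2.69-fold and H2-Ab1 2.62-fold higher. With equal weight for each cell H2-Aa was 2.36-fold, H2-Eb1 1.75-fold, H2-Ab1 1.47-fold and Cd74 1.45-fold higher, and with the Mmp12-led cluster counted as microglia-like the class II median was -0.29. It was 0.14 with no minimum of UMIs. Macrophage markers stood at 139 CPM in these cells. The class I genes H2-Q7, H2-Q6 and H2-D1 were 2.38-fold, 1.75-fold and 1.69-fold higher. Complement had 12 of 13 genes higher (median 0.46), with C4b 14.6-fold higher (7.01 to 36.7), 22.6-fold without the Gpnmb-led cluster, and at a log2 ratio of 4.64 with equal weight for each cell. Cytokine and chemokine genes had 13 of 21 higher (median 0.17, percentile 92.75), among them Ccl7 (11.3-fold, 6.87 to 19.9), Cxcl2 (3.18-fold) and Il1b, which encodes interleukin-1 beta (3.17-fold, and 1.87-fold without the Gpnmb-led cluster). For Ccl7, 1 P23H cell held 159 of 484 UMIs and 51 cells held 88.0%. Whether its RNA came from macrophage-like cells was not tested here. Ccr2 had 14 UMIs against 1, a ratio of 5.21 (0.793 to 221).

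Metabolic and cell cycle lists were higher in P23H. Lipid handling had 19 of 24 genes higher (median 0.38), oxidative phosphorylation 26 of 27 (median 0.46), glycolysis 15 of 17 (median 0.24) and the lysosome and phagocytosis list 20 of 29 (median 0.22). Axl, a receptor for apoptotic cells, was 2.43-fold higher, the glycolytic enzyme gene Pkm 1.74-fold and the respiratory chain gene Ndufa1 1.72-fold higher. The cell cycle list had 15 of 20 higher (median 0.71), with Tk1 3.84-fold and Birc5 3.28-fold higher. Ribosomal protein genes were higher, 21 of 21 (median 0.46), and the iron and antioxidant list had 12 of 21 higher (median 0.08, percentile 85.0), with Srxn1 at 0.80 and Slc7a11 at 0.66, which without the Gpnmb-led cluster were at 0.04 and -0.51. The immediate early list had 17 of 20 genes lower (median -0.51), among them Fosb (-1.02). The lowest P23H genes were Plk3 (9.13-fold lower, 7.86 to 10.6), Yrdc (8.10-fold), Klf2 (7.97-fold), the coactivator gene Cited2 (6.59-fold), Jund (5.96-fold) and the growth factor gene Hbegf (5.85-fold). Pnrc1, Cebpa, Zfand5 and Snta1 were 4.85-fold, 4.78-fold, 4.54-fold and 4.50-fold lower. All 50 of the lowest P23H genes were lower in macrophage-like cells too (median -1.20), and their median GC content was 52.3%.

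In the aging library, microglia-like cells had higher interferon-response and MHC class II transcripts, higher levels of the chemokine genes Cxcl13, Pf4 and Ccl7 and a lower level of the microglial gene Fcrls. Cxcl13, a chemokine that draws B cells (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068), was at least 94.4-fold higher, with 255 UMIs against 0 in the young control, from 29 of 410 aging cells. Pf4, a chemokine gene also used as a macrophage marker, was 36.5-fold higher (16.5 to 101) and Ccl7 20.2-fold (12.2 to 35.8). These transcripts sat in few cells: Pf4 UMIs came from 21 of 410 aging cells and Ccl7 UMIs from 37. Single aging cells held 84 of 255 Cxcl13, 63 of 197 Pf4 and 154 of 291 Ccl7 UMIs. The intervals treat the UMIs of a cell as independent. Fcrls, an Fc receptor-like gene (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), was 4.05-fold lower (3.43 to 4.80). With equal weight for each cell Pf4 was 14.4-fold and Ccl7 9.51-fold higher. Macrophage markers stood at 236 CPM in aging microglia-like cells against 34.0 in the young control, and relative to macrophage-like cells of the library the levels of Ccl7, Pf4, H2-Aa and H2-Eb1 lay within the range of those markers.

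The degeneration-associated list had 18 of 28 members higher and 10 lower in aging, with a median log2 ratio of 0.17 (0.15 to 0.35, percentile 97.9), and of 0.07 without the Gpnmb-led and Cst7-led clusters. Apoe was 2.98-fold (2.85 to 3.11, and 1.91-fold with equal weight for each cell), Cst7 3.19-fold (2.32 to 4.43, and 4.90-fold without the Gpnmb-led cluster), Lgals3 2.73-fold (1.67 to 4.59) and Trem2 1.18-fold higher. Lgals3 reached 6.97-fold with equal weight for each cell, and came from 12 aging and 8 young control cells. Gpnmb had 18 UMIs against 2 (9.99-fold, 2.39 to 88.8, and 18.4-fold with equal weight for each cell), with 14 of the 18 from 1 aging cell. Ch25h had 40 UMIs against 1. Spp1 was 5.92-fold lower (3.35 to 11.2), with 14 UMIs against 92, of which 64 came from 1 young control cell. The homeostatic list had 12 of 20 members lower (median -0.06, -0.11 to -0.03, percentile 24.9), with P2ry12 at -0.28, Tmem119 at -0.21, Cx3cr1 at 0.08, Crybb1 at 0.47 and Siglech at 0.34. Ccr2 had 0 UMIs against 1, too few for a ratio.

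All 20 interferon genes were higher in aging (median 0.91, 0.77 to 1.10). Ifi27l2a (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680) was 5.05-fold (4.31 to 5.95), the antiviral gene Rsad2 4.25-fold (2.91 to 6.36), Oasl2 3.79-fold and Mx1 3.01-fold higher. Ifi27l2a UMIs came from 196 of 410 aging cells and Rsad2 UMIs from 34. The niacin and ketone body receptor gene Hcar2 was 4.04-fold and the cytokine receptor gene Crlf2 3.91-fold higher. Of MHC class II genes 7 of 8 were higher (median 0.80), 4 of them by counting interval, with H2-Aa 6.93-fold, H2-Eb1 5.44-fold, Cd74 2.67-fold and H2-Ab1 2.17-fold higher. With equal weight for each cell H2-Aa was 2.56-fold and H2-Eb1 2.23-fold higher. MHC class I had 11 of 12 higher (median 0.49), led by H2-Q7 (2.14-fold), Psmb9 (1.64-fold) and Tap1 (1.61-fold). Cytokine and chemokine genes had 12 of 21 higher (median 0.23, and -0.05 with thinned cells), among them Cxcl1 with 55 UMIs against 2, Cxcl2 (3.43-fold, and 1.68-fold with equal weight for each cell) and Ccl2 (2.11-fold). Complement had 8 of 11 higher (median 0.27, percentile 94.6), with Cfp, which encodes properdin, at 40 UMIs against 1.

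Lower in aging were the iron and antioxidant list, with 16 of 21 genes lower (median -0.33, percentile 0.02), and the immediate early list, with 17 of 20 lower (median -0.19). The glutathione synthesis genes Gclc and Gclm had log2 ratios of -1.10 and -1.02, and the redox enzyme gene Srxn1 was 2.56-fold lower, while Cp, which encodes ceruloplasmin, had 28 UMIs against 2. Atf3 was at -0.61 and Egr1 at -0.35. Hbegf, Plk3, the phosphatase gene Dusp5, Zfand5 and the kinase gene Sgk1 were 3.72-fold, 2.71-fold, 2.65-fold, 2.62-fold and 2.56-fold lower. Klf2, Tgif2 and Jund were 2.52-fold, 2.42-fold and 2.25-fold lower. The cell cycle list had 18 of 20 higher (median 0.66), with Rrm2 4.19-fold and Birc5 3.96-fold higher, oxidative phosphorylation 23 of 27 (median 0.35), with Ndufa1 1.84-fold, and ribosomal protein genes 21 of 21 (median 0.36). Lysosome and phagocytosis genes had 16 of 28 higher (median 0.07, percentile 85.4), with Gas6 1.67-fold higher, glycolysis 9 of 17 (median 0.03, percentile 66.4), and lipid handling 11 of 22 (median -0.06, percentile 27.5), with Dgat2 at -1.59.

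**Figure D2:**
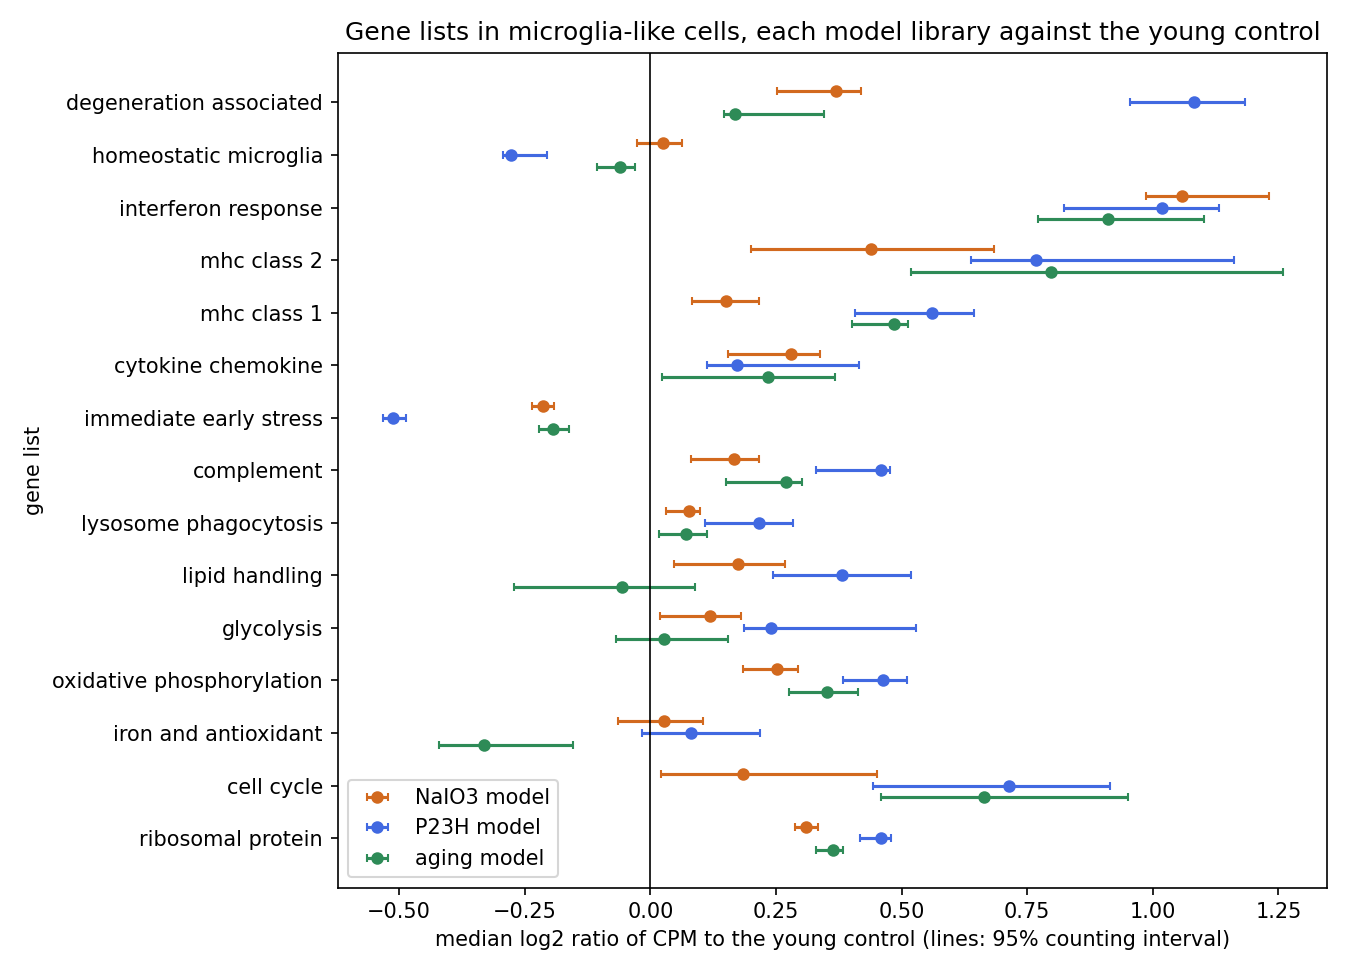
Median log2 ratio of CPM to the young control (x axis) of each of the 15 gene lists (y axis) in microglia-like cells of the 3 model libraries, with 95% counting intervals as lines. The degeneration-associated list stands at 1.08 in P23H, 0.37 in NaIO3 and 0.17 in aging, and the interferon list between 0.91 and 1.06.

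Directly against the NaIO3 library, of the same age, P23H microglia-like cells had higher degeneration-associated genes and lower homeostatic genes. H2-M2 was 45.1-fold (28.5 to 75.6), Cst7 6.92-fold (6.08 to 7.91), Fabp5 4.26-fold (3.72 to 4.90), Apoe 4.04-fold (3.97 to 4.11) and Gdf15 3.42-fold higher (3.03 to 3.86). Apoe was also higher in photoreceptor-like cells, by 9.60-fold, and by 3.30-fold with equal weight for each cell. Without the Gpnmb-led cluster H2-M2 was 5.03-fold higher. Lgals3 was 2.44-fold (2.22 to 2.67) and the growth factor gene Igf1 4.19-fold higher (13.2-fold without the Gpnmb-led cluster), while Trem2 was at 1.03-fold. The degeneration-associated list had 25 of 29 members higher (median 0.48, 0.43 to 0.51, percentile 100) and the homeostatic list 17 of 20 lower (median -0.25, -0.28 to -0.21, percentile 0.18), with Mef2c at -0.42, P2ry12 at -0.34, Tmem119 at -0.25 and Cx3cr1 at -0.20. Hbegf was 3.25-fold, the transcription factor gene Creb5 2.45-fold, Ifitm10 2.39-fold, Gtf2b 2.32-fold and Lrba 2.28-fold lower. Ccr2 had 14 UMIs against 4 (6.57-fold, 2.06 to 27.4).

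Over all measured genes the median log2 ratio of P23H to NaIO3 was -0.11. The interferon list had 15 of 20 members lower in P23H than in NaIO3 (median -0.13, percentile 32.7), but by counting interval 5 were higher, 6 lower and 9 included no change, with Ifit1 at -1.09 and Mx1 at -0.87 but Ifi27l2a at 0.72. That median turned to 0.06 with thinned cells and 0.11 with equal weight for each cell. MHC class II had 7 of 8 higher (median 0.43), with H2-Aa 2.35-fold (1.51-fold with equal weight for each cell) and Cd74 1.89-fold higher, and MHC class I 10 of 13 (median 0.28), with B2m 1.48-fold higher. Complement had 11 of 13 higher (median 0.29), with C4b 7.71-fold higher, and cytokine genes 12 of 22 (median 0.12), with Cxcl2 2.49-fold higher and Il6 at -1.86. Lipid handling had 18 of 25 higher (median 0.32), with the sterol synthesis gene Sqle 3.35-fold higher and Abcg1 at -1.46, lysosome and phagocytosis 22 of 30 (median 0.25), with Ctsb 1.60-fold, glycolysis 13 of 17 (median 0.27), with Pgk1 1.46-fold, and oxidative phosphorylation 25 of 27 (median 0.18). The cell cycle list had 16 of 20 higher (median 0.34), with Mki67 1.89-fold, ribosomal proteins 21 of 21 (median 0.15), and the iron and antioxidant list 14 of 21 (median 0.18, and -0.10 without the Gpnmb-led cluster). The immediate early list had 14 of 20 lower (median -0.21), although Ier5 was 2.51-fold higher.

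**Figure D3:**
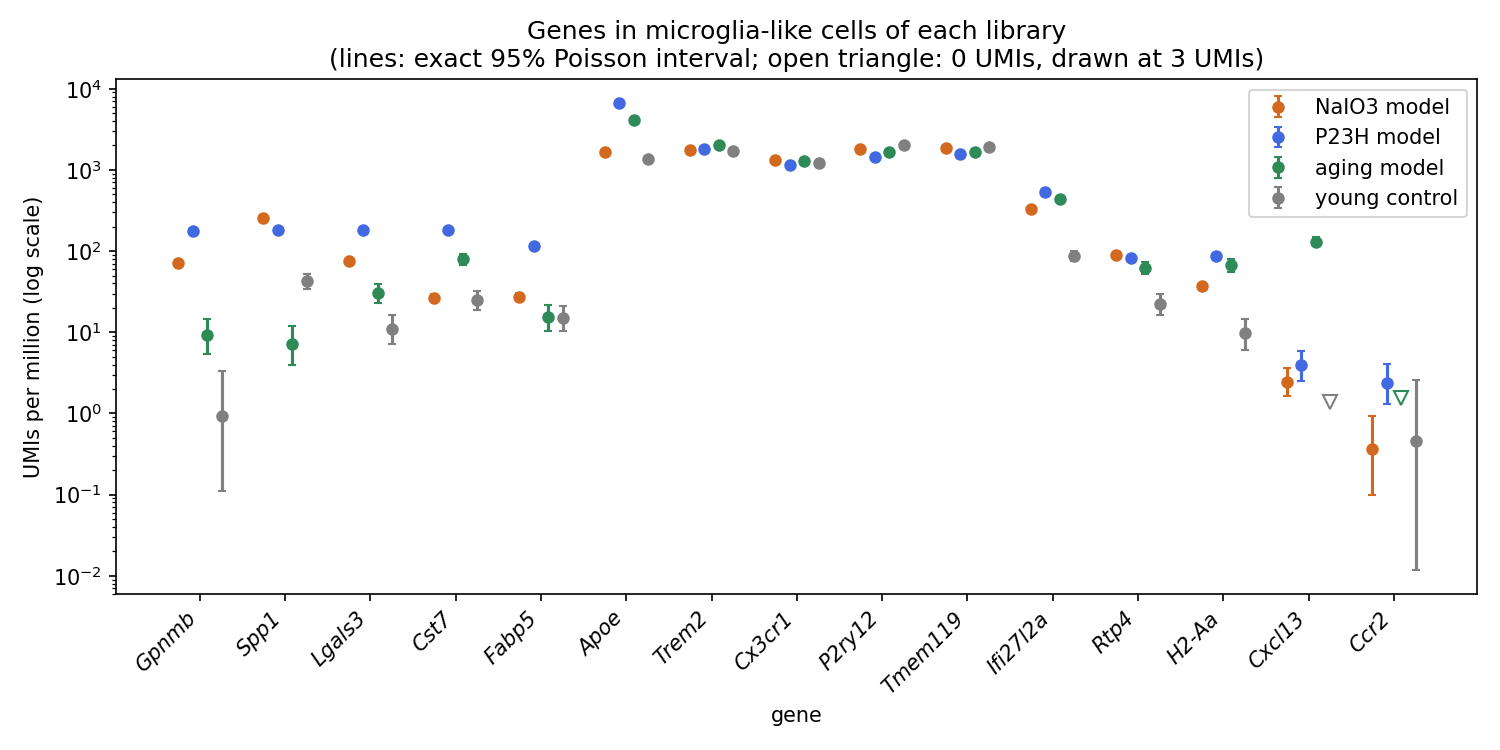
CPM (log-scale y axis) of 15 named genes (x axis) in microglia-like cells of the 4 libraries, with exact 95% Poisson intervals as lines and open triangles at 3 UMIs where none was found. Gpnmb runs from 0.920 in the young control to 177 in P23H, while Trem2 lies between 1726 and 2034 in the 4 libraries.

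Cells with a high share of degeneration-associated UMIs were most frequent in the P23H library. At 2000 UMIs per cell, 29.6% of P23H microglia-like cells (26.7 to 32.7, 281 of 948) lay above the 95th percentile of the young control, against 13.3% in aging (10.1 to 17.1, 51 of 383), 5.53% in NaIO3 (4.59 to 6.60, 116 of 2097) and 5.15% in the young control itself (22 of 427). The line is a point in a continuous range, at 4.68% of a cell's UMIs, and 180 P23H cells lay within 0.5 percentage points of it. Median shares were 3.90% in P23H, 3.15% in aging, 3.00% in NaIO3 and 3.05% in the young control. The P23H share was 16.4% with the Mmp12-led cluster counted as microglia-like and 17.3% with the top 5% of doublet scores removed. For interferon genes the shares above their own line, at 0.350% of UMIs, were 17.7% in P23H, 14.1% in NaIO3, 13.6% in aging and 4.92% in the young control, but 912 of 948 P23H and 1988 of 2097 NaIO3 cells lay within 0.5 percentage points of that line. For homeostatic genes the line was 9.90%, and 3.38%, 5.72%, 7.31% and 4.92% lay above it.

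**Figure D4:**
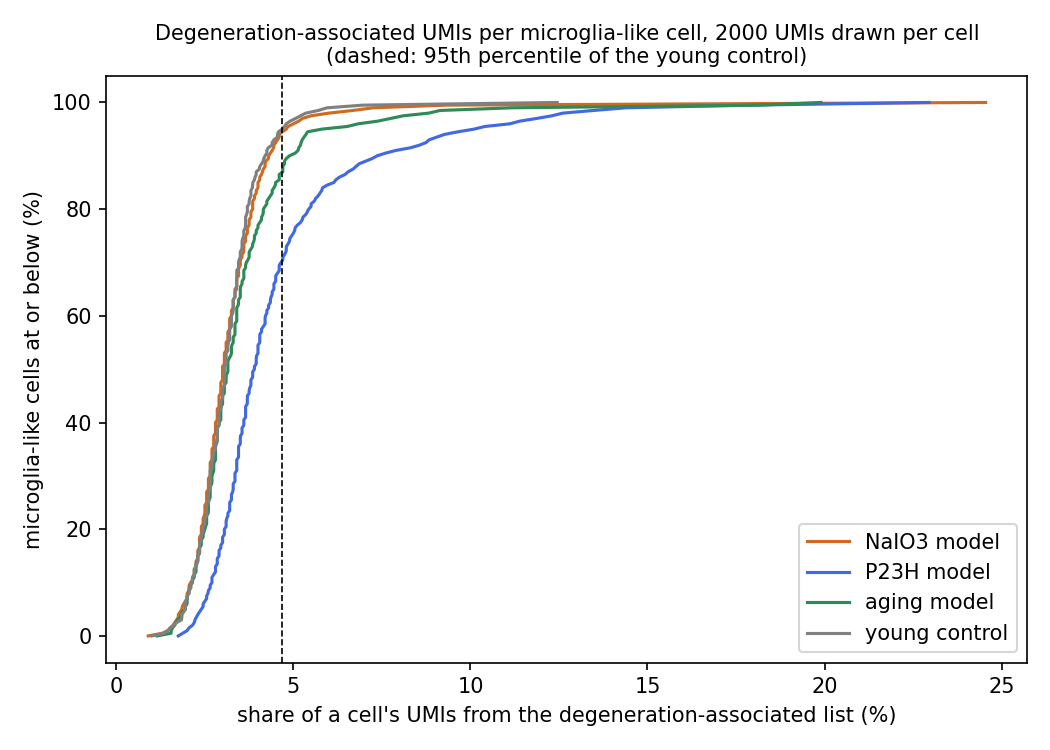
Cumulative percent of microglia-like cells (y axis) by the share of their UMIs from the degeneration-associated list (%, x axis) after thinning to 2000 UMIs, 1 line per library, with the 95th percentile of the young control dashed. The P23H line lies to the right, with a median of 3.90% against 3.05% in the young control, while the NaIO3 median is 3.00%.

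Lgals3 was found in a small part of the microglia-like cells. With each cell thinned to 1000 UMIs, 3.93% of P23H cells (2.81 to 5.34), 1.74% of aging cells, 1.14% of NaIO3 cells and 0.680% of young control cells had a UMI, and before thinning 11.9%, 2.93%, 3.62% and 1.79%. In photoreceptor-like cells, which should lack it, 1 of 114 P23H cells (0.877%) had one, as did 0 of 55 NaIO3, 0 of 40 aging and 0 of 49 young control cells, which allow shares of up to 5.45%, 7.50% and 6.12% by the limit of 3 counts. Median UMIs before thinning were 4704, 5352, 4453 and 4655.5 in microglia-like cells of NaIO3, P23H, aging and young control, and 909, 1206, 1257.5 and 1235 in photoreceptor-like cells. The P23H share and its background have overlapping intervals at this depth (background 0.0222 to 4.79), but the levels over all UMIs were apart, at 183 CPM in microglia-like and 5.60 CPM (2 UMIs) in photoreceptor-like cells of P23H. Of the P23H microglia-like UMIs 93.0% came from 51 cells, and single cells held up to 160 Lgals3 UMIs in P23H and 221 in NaIO3.

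The 3 models shared 1 control, whose counting error alone brings some likeness to their ratios. Across genes, which are not independent replicates, the ratios of NaIO3 and P23H had r = 0.774, of P23H and aging 0.757 and of NaIO3 and aging 0.612. Simulated libraries that differed by counting error only gave r of 0.780, 0.588 and 0.627, which hold no real differences and so are no measure for the observed r. The observed covariances were 0.159, 0.133 and 0.0811, against 0.0101, 0.0103 and 0.00987 in the simulations, so counting error of the control accounts for little of them. With a separate part of the control for each model r was 0.648, 0.649 and 0.475. Neither comparison can show a real difference of the control library from the others, which all ratios would share. Of the 100 highest genes, NaIO3 and P23H shared 51 (52.2 in the simulations, 33 with a split control), P23H and aging 55 (36.45 and 44) and NaIO3 and aging 51 (38.8 and 30). Of the 100 lowest they shared 50 (45.7 and 44), 46 (28.3 and 40) and 36 (31.4 and 32). The simulated genes were ranked by counting error alone, so the simulated overlaps, like the simulated r, are no measure for the observed ones.

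Outside microglia, both degeneration models had enough macrophage-like and photoreceptor-like cells to compare, 190 and 187 in P23H and 197 and 133 in NaIO3. Macrophage-like cells of P23H had more C4b (5.67-fold, 4.43 to 7.36), a complement gene also higher in its microglia-like cells, and more Slc25a33 (5.20-fold), Metrnl (4.04-fold), Il10 (3.81-fold), which encodes an anti-inflammatory cytokine, and C2 (2.98-fold). They had less of the chemokine genes Ccl5 (4.50-fold lower) and Cxcl10 (2.25-fold), the collagenase gene Mmp13 (3.87-fold), Ppp1r10 (2.51-fold) and the adhesion gene Icam1 (2.13-fold). Lgals3 was 1.62-fold and Apoe 1.29-fold higher, Trem2 was at 0.970-fold and Ccr2 at 1.66-fold (0.838 to 3.41). P2ry12, Tmem119 and Cx3cr1 had log2 ratios of -0.53, -0.51 and -0.42.

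Photoreceptor-like cells of P23H had more metallothionein Mt2 (71 UMIs against 1, 36.1-fold, 6.28 to 1447), Cebpd (34.6-fold, and 104-fold with equal weight for each cell), Bst2 (21.9-fold), Bri3 (20.9-fold, and 7.48-fold with doublets kept) and Pcolce (at least 10.4-fold, 61 UMIs against 0). Slc16a3, Terf1, Wisp1, Bhlhe41 and Lyrm9 were 5.65-fold, 5.02-fold, 4.32-fold, 3.84-fold and 3.60-fold lower. Terf1 and Lyrm9 had ratios of 0.300 and 0.423 with equal weight for each cell. Apoe, which stood at 69432 CPM in macrophage-like cells of P23H and so could enter as free RNA or in doublets, was 9.60-fold higher (7.80 to 11.9), and 3.30-fold with equal weight for each cell. Lgals3 had 2 UMIs against 0 and Ccr2 0 in both, too few for a ratio. Trem2, P2ry12, Tmem119 and Cx3cr1, which are microglial, had 41, 18, 23 and 18 UMIs in P23H and 26, 13, 11 and 15 in NaIO3.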

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

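The alternative without the Gpnmb-led cluster was chosen after the result was seen. Of 45 genes compared across the 3 models, 1 was at least 2-fold higher than the young control in 1 model and at least 2-fold lower in another. Its counting intervals had to exclude no change in both. Smaller differences in direction were not flagged. Spp1, which encodes osteopontin, had a log2 ratio of 2.58 in NaIO3 and 2.09 in P23H but -2.57 in aging. The difference between the models was not tested, since each is 1 library. The NaIO3 and young control values rest on few cells: 1 NaIO3 cell held 1722 of 2777 UMIs and 1 young control cell 64 of 92. Without the top cell of each library the levels were 96.2 CPM in NaIO3, 148.7 in P23H, 4.08 in aging and 12.9 in the young control, and without the Gpnmb-led cluster the NaIO3 log2 ratio was -0.18.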

How the results depend on the processing

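Alternatives marked as added were chosen after seeing the data. In all 16 settings the degeneration-associated median kept its direction: 0.13 to 0.41 in NaIO3, 0.72 to 1.17 in P23H, 0.07 to 0.37 in aging and 0.34 to 0.59 in P23H against NaIO3. The homeostatic median ran from -0.28 to -0.12 in P23H, from -0.27 to -0.09 in P23H against NaIO3, from 0.00 to 0.08 in NaIO3 and from -0.16 to -0.01 in aging. Library order is NaIO3, P23H, aging, young control. With no filter on cells, the P23H microglia-like share was 51.7% and the aging cytokine list reversed to -0.012. With the stricter cell filter the microglia-like shares were 87.3%, 65.2%, 55.9% and 81.1%, the NaIO3 degeneration-associated median 0.13 and the share of P23H cells above the line 26.2%, and in NaIO3 the MHC class II (-0.70), cytokine (-0.060) and cell cycle (-0.083) lists reversed. Doublets kept gave microglia-like shares of 83.0%, 57.8%, 51.9% and 72.9%, the lower cluster resolution 83.2%, 58.5%, 52.4% and 72.8%, an immune denominator (added) 87.1%, 65.4%, 54.9% and 82.7%, and the unnamed cluster counted in (added) 83.3%, 58.5%, 52.4% and 72.8%. Removing the top 5% of doublet scores (added) gave shares of 81.5%, 59.3%, 55.6% and 72.4%, degeneration-associated medians of 0.14 (NaIO3), 0.72 (P23H) and 0.40 (P23H against NaIO3), homeostatic medians of 0.077 (NaIO3) and -0.16 (aging), and 4.08% of NaIO3 and 17.3% of P23H cells above the line. There MHC class II reversed in NaIO3 (-0.80) and P23H (-0.35), and cytokines in NaIO3 (-0.036) and aging (-0.063). Counting the Mmp12-led cluster as microglia-like (added) gave shares of 81.3%, 59.1%, 53.2% and 72.5%, degeneration-associated medians of 0.14 (NaIO3), 0.86 (P23H) and 0.37 (aging), homeostatic medians of 0.064 (NaIO3) and -0.15 (aging), and 3.33% and 16.4% of NaIO3 and P23H cells above the line. There MHC class II reversed in NaIO3 (-0.85) and P23H (-0.29), cytokines in NaIO3 (-0.017) and aging (-0.047) and lipid handling in NaIO3 (-0.030). Adding that cluster alone is enough to reverse MHC class II. With the top 5% of doublet scores removed, 93 of 185 NaIO3, 73 of 168 P23H and 37 of 56 young control macrophage-like cells were classed as microglia-like. With the stricter filter they were 24 of 188, 31 of 181 and 11 of 53. With those cells left out of the models and the young control (added) the MHC class II medians were 0.37 and 0.62. They were 0.48 and 0.78 with the stricter filter. None was reversed, so the reversals came from those cells, which lay in the young control too. Thinned cells gave a P23H degeneration-associated median of 0.93 and homeostatic medians of -0.024 (aging) and -0.20 (P23H against NaIO3), and reversed glycolysis (-0.031) and cell cycle (-0.056) in NaIO3, cytokines in aging (-0.053) and interferon in P23H against NaIO3 (0.056). Equal weight for each cell gave an aging homeostatic median of -0.015 and an interferon median of 0.11 in P23H against NaIO3, reversed. TMM moved P23H against NaIO3 by 0.11 on the log2 scale for every gene (0.09 or less in size elsewhere), with homeostatic medians of -0.19 (P23H) and -0.14 and a degeneration-associated median of 0.59 (P23H against NaIO3), and Cx3cr1 in P23H reversed to 0.0042. Totals without mitochondrial and ribosomal genes gave homeostatic medians of 0.066 (NaIO3) and -0.0088 (aging), and a minimum of 50 UMIs a degeneration-associated median of 0.10 in aging. The 90th percentile put 11.0%, 40.0% and 19.3% of NaIO3, P23H and aging cells above the line, and the list without 4 abundant members 21.2% of P23H and 9.40% of aging cells. Without the Gpnmb-led cluster (added) degeneration-associated medians were 0.24 (NaIO3), 0.82 (P23H) and 0.36 (P23H against NaIO3), homeostatic medians -0.14 (P23H) and -0.11 (P23H against NaIO3), and 7.06% of NaIO3 and 25.1% of P23H cells lay above the line. There the iron and antioxidant list (-0.10) and Srxn1 (-0.15) in P23H against NaIO3, Spp1 in NaIO3 (-0.18), and Cx3cr1 (0.039) and Slc7a11 (-0.51) in P23H reversed. Without the Cst7-led cluster too (added) the medians were 0.24, 0.74, 0.072 (aging) and 0.34 (P23H against NaIO3), homeostatic -0.12 and -0.093, P23H cells above the line 22.3%, and the iron and antioxidant list reversed again (-0.10). Except for MHC class II, the cause was not tested. The higher resolution left all 15 main values within their intervals, as did thinning to 1000 UMIs, no thinning and no minimum for those they apply to. Among other results, named genes stayed within their interval in 1125 cases, moved in 156 and reversed in 5, other lists 638, 122 and 20, and other class shares 153 and 15 with no reversal possible. No paired analysis was possible because each group is 1 library, which also allows no test. Depth limits ratios of genes with few UMIs in the young control, such as Gpnmb (2) and Ch25h (1), and shares of cells with a UMI.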

Other observations

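The tests of the immediate early list and of doublets in the T-cell-like cluster were chosen after the result was seen. T-cell-like cells lay in different clusters by library, with 84 of 116 aging cells in a cluster led by Tcrg-C2, Cd8a and Cxcr6, called Cd8a-led here. The other cluster held 106 of 111 P23H and 29 of 36 NaIO3 cells, so values for this class compare libraries of different cluster mix. Cd8a, the coreceptor of cytotoxic T cells, stood at 866 CPM (95% interval 762 to 981) in 116 aging T-cell-like cells, 381 in 36 NaIO3 cells and 227 in 111 P23H cells, and the other CD8 chain, Cd8b1, at 960, 689 and 625. Xcl1, a chemokine gene, stood at 1065 CPM against 181 and 218, the residence marker Cxcr6 at 835 against 145 and 212, the checkpoint receptor gene Pdcd1 at 475 against 145 and 38.9, and the granzyme gene Gzmk at 402 against 81.6 and 65.8. Genes of naive T cells were the other way: Lef1 stood at 45.4 CPM in aging against 317 in NaIO3 and 404 in P23H, and Sell at 31.4 against 317 and 221. Within the Cd8a-led cluster, in 84 aging, 7 NaIO3 and 5 P23H cells, Cxcr6 stood at 930, 935 and 987 CPM, Xcl1 at 946, 877 and 1571, Cd8b1 at 1411, 1345 and 224, Pdcd1 at 636, 935 and 180 and Gzmk at 615, 526 and 44.9 (P23H interval 1.14 to 250). In the other cluster, in 32 aging, 29 NaIO3 and 106 P23H cells, the libraries differed as well, so cluster mix was not the only difference. There Cxcr6 stood at 655, 0 and 157 CPM, Xcl1 at 1289, 53.7 and 122 and Pdcd1 at 171, 0 and 28.8. Lef1 stood at 101, 376 and 432, Cd8b1 at 111, 569 and 654, and Gzmk at 0, 0 and 67.3. The young control held 5 T-cell-like cells, too few to compare. These values come from few cells of 1 library each and were not tested.

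Genes lower in microglia-like cells of the NaIO3 and P23H libraries, the lowest 50 of each, may reflect a difference between whole libraries rather than one of microglia. In macrophage-like cells all 50 were lower, by a median log2 ratio of -1.53 (NaIO3) and -1.20 (P23H), and in lymphocyte-like cells, where 29 and 39 of them could be measured, 28 and 33 were lower, with medians of -2.02 and -0.92, values that this explanation needs and that could have come out otherwise. GC content bias stays open as well: median transcript GC of the lowest 50 was 52.8% and 52.3%, above the upper limit of random sets (51.7% and 52.0%), although across all genes the ratio hardly followed GC (r = -0.02 and 0.06). For a stronger immediate early response to dissociation in the young control, the medians of that list were -0.21 (-0.24 to -0.19) and -0.51 (-0.53 to -0.49). The lowest 50 had medians of -1.87 and -1.54. They were picked in these data as the lowest, so a list fixed beforehand had to fall less. Among random lists the immediate early list lay at percentile 0.01 (NaIO3) and 0.0 (P23H). Its members spread widely, with an SD of 0.878 and 0.862, which is not an error of the median. Of the lowest 50, picked from 2751 (NaIO3) and 2700 (P23H) genes, 3 and 2 are on this list of 20. A response of the list, or of part of it, therefore cannot be told apart. A response of all immune cells to the models stays open and untested, since model and library are the same thing here.

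The 10 highest genes of aging microglia-like cells could be RNA carried in from macrophage-like cells, free or in doublets. Their median level in microglia-like cells, less that of the young control, was 37.6% of the level in macrophage-like cells, 11.4 times that of macrophage markers (3.30%). The 10 genes were picked in these same data for a high ratio to the young control, so this median cannot decide for the set as a whole. Of the 10, 6 stood above the highest marker (8.20%), from Hcar2 at 31.6% to Ifi27l2a at 75.7%. That is more than RNA carried in at the rate of the markers would bring. For Ccl7, Pf4, H2-Aa and H2-Eb1, which did not stand above it, carried-over RNA stays open. Age as a biological difference stays open and untested for all 10.

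The Cd8a-led T-cell-like cluster held 84 aging cells among its 96 cells, with 7 from NaIO3, 5 from P23H and 0 from the young control. Its 10 leading genes also held Tcrg-C2, which came first, and Tcrg-C4. Doublets of T cells with microglia are argued against, since microglia markers in its aging cells stood at a median of 0.636% of their level in microglia-like cells. Of T-cell-like cells without a Cd8a or Cd8b1 UMI, 2 of 30 in aging (6.67%, 0.818 to 22.1) and 2 of 76 in the other libraries (2.63%) lay in it. Cd8a and Cd8b1 are themselves among its 10 leading genes. This split therefore cannot show whether it took in aging T-cell-like cells at large. Whether its cells are a kind of cell or are set apart by the aging library cannot be told apart. Of cells with such a UMI, 10 of 76 from the other libraries lay in it (13.2%, 6.49 to 22.9), against 82 of 86 in aging (95.3%), and the others may be T cells of another state. An increase of such cells with age stays open and untested, as 1 library per group cannot show it.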
